A study of Mus musculus with 12 samples.

How the data were processed

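The data are RNA-seq counts of mouse Hepa1 hepatoma cells and primary MEFs labelled Bach1 knockout, 3 libraries in each of 4 groups. Per the labels' protocols, immortalised MEFs conditioned the medium, which held 10% fetal bovine serum, for 48 h. Recipient cells stayed in it for 4 days with 0.1 mM 2-mercaptoethanol and 0.4 mg/mL vitamin E, and it was replaced daily. Libraries were made from 100 ng of total RNA with the NEBNext Ultra II RNA kit, per the labels' protocols.

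The deposited files give raw read counts per Ensembl gene, as 1 file per sample and 1 table for the series, and 0 values differed between them. Per the submitters' processing notes, reads were handled with FastQC 0.11.9, Trimmomatic 0.39, STAR 2.7.10a and HTSeq 0.9.1 on GRCm38 (mm10). The annotation release and the strand setting are not given in the sources used here. The table holds 55487 genes and 5 HTSeq summary lines, which were set apart. Multi-mapped reads are not counted. Names and coordinates came from GENCODE M21, which named 55227 gene identifiers and left 260 without a name. The kit is named without a strand-specific variant, and 92 of the 256 named genes overlap an annotated gene on the other strand, whose reads were not told apart.

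Groups were taken from the sample titles. Total counts per library ran from 18.58 M to 23.4 M. Between 2.00 and 2.58% of reads fell on no gene and 3.66 to 4.03% were ambiguous, and 19342 to 21374 genes were detected. A library's floor was set at 3 counts, and floors and intervals cover counting error only. The confidence level is 95%. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The biological coefficient of variation was 3.08% in Hepa1 and 2.45% in MEFs. Replicate numbers were not treated as pairs. Deviations from the group mean in control and ferroptotic libraries of the same number correlated at only -0.0143 to 0.0366. The best match had the same number for 1 Hepa1 and 1 MEF replicate, so no pairing was seen, though this cannot exclude one.

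Each cell type was tested on its 6 libraries with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, after filterByExpr and TMM scaling, with Benjamini-Hochberg adjusted p under 0.05 as a call. The difference between responses was tested as an interaction over all 12 libraries. The overlap of calls was tested with Fisher's exact test among genes tested in both. CPM in the comparisons are normalised within each cell type's fit unless called plain, and those of the Bach1, Alb and Col1a2 label checks are plain.

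Gene lists (38, of which 29 are processes and 9 are cell types) were tested with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01, for lists with at least 5 measured members. The test was repeated with an estimated correlation and with fry, whose p tests whether a list's genes move one way without comparing them with other genes. With the preset correlation camera takes its degrees of freedom from the number of genes. With an estimated correlation it takes the few residual ones of the libraries, so p can rise without any correlation between genes. Adjusted p-values of genes are from edgeR and those of lists from camera unless another tool is named. The count of changed members uses adjustment over all genes, and the count adjusted over the list alone is given at the end of each comparison where it differs.

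The tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names 12 fixed genes and, in each cell type, the 10 protein-coding genes with the largest rise and the 10 with the largest fall among called genes with a mean of at least 1 CPM and no overlap between the groups (non-overlap arises by chance in 10% of comparisons of 3 with 3). It adds up to 4 members of each called list and up to 2 of other lists with the smallest adjusted p, 5 genes per direction for the interaction, and 5 per direction for genes changed in both. Not every gene that the rule names is given in the text. Genes named outside the rule were chosen after their values were seen, and the text says so where they appear.

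The pipeline was tested on simulated data with the depth and dispersion of these libraries. In Hepa1 it recovered 56.0% of genes changed 1.25-fold and 89.8% of genes changed 2-fold, with 10.8% of 130 calls false. In MEFs it recovered 70.0% and 93.9%, with 5.75% of 139 calls false. For the interaction it recovered 38.8% and 66.7%, with 5.95% of 84 calls false. The planted list was called, and 0 of 30 unchanged lists were. Genes were simulated independently of each other, so this does not show how the list tests act on correlated genes. Few genes were changed in the simulation, so its rates need not hold in data where 58.1% of Hepa1 genes were called.

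Alternatives were DESeq2 size factors, no scaling, the DESeq2 1.42.0 Wald test, limma-voom, other count filters, a replicate block, 1 fit for all libraries, a minimum effect and leaving out each library. Offsets for GC content and length, a minimum fold of 1.2, genes tested in both cell types and lists without shared members were added after seeing the data. Figures were drawn with matplotlib 3.10.9.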

Results

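RNA sequencing was used to measure gene expression in 12 mouse libraries that fall into 4 groups of 3. Hepa1 is a mouse hepatoma line, labelled wild type, and the other cells were primary mouse embryonic fibroblasts (MEFs) labelled Bach1 knockout. Both were cultured for 4 days in medium conditioned for 48 h by immortalised MEFs, either control cells or cells that re-expressed Bach1 and were labelled ferroptotic. These are called the control and the ferroptotic medium here. Ferroptosis is an iron-dependent form of cell death, and BACH1 is a transcription factor that represses genes of heme, iron and glutathione metabolism. The title of the series names cellular senescence and secreted FGF21, so the comparisons ask what the medium of ferroptotic cells changes in each recipient cell. The libraries held 18.58 M to 23.4 M reads assigned to genes, and 3 counts in a single library correspond to 0.128 to 0.161 CPM, counts scaled to a common library total.

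Bach1 (ENSMUSG00000025612, chromosome 16, 87698945 to 87733346, GRCm38) was read in all 4 groups. Its level was 142 ± 4.22 CPM in Hepa1 in control medium and 121 ± 5.50 CPM in ferroptotic medium (SD, n = 3 each, plain CPM). In the MEFs labelled knockout it was 77.4 ± 4.78 and 75.2 ± 2.75 CPM. The counts cover whole genes and the labels do not say which exons were deleted, so these reads do not check the deletion. Alb, the gene of serum albumin, had 0 reads in all MEF libraries and 1988 reads in Hepa1 in control medium. Col1a2, a type I collagen gene, had 1014955 reads in MEFs in control medium and 38 in Hepa1 in control medium. Not every marker parted the cells, as genes looked at after their values were seen show. In Hepa1 in control medium the liver genes Afp and Hnf4a had 3470 reads and 1 read, and the collagen gene Col1a1 had 87993.

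**Figure D1:**
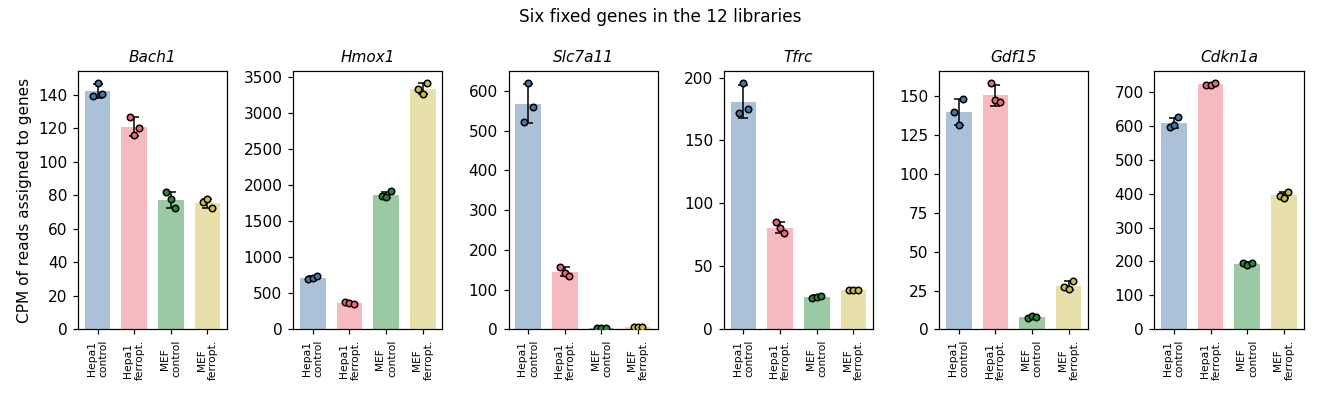
Plain CPM (y axis, each panel with its own scale) of 6 genes in the 4 groups (x axis), with bars for group means, error bars for the SD and points for the 3 libraries of each group. Hmox1 stood at 717 and 360 CPM in Hepa1 in control and ferroptotic medium and at 1864 and 3338 CPM in MEFs, so the direction of its change differed between the cell types.

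In Hepa1 cells, G2 and M phase genes were higher, and NF-kB response genes and targets of NRF2 and BACH1 were lower, in the ferroptotic than in the control medium. These list calls were lost with an estimated correlation (adjusted p = 0.183, 0.0692 and 0.346). Mki67, a proliferation marker, went from 13.1 ± 2.65 to 81.4 ± 4.84 normalised CPM (SD, n = 3), a log2 change of 2.64. Slc7a11, the cystine transporter that supplies glutathione synthesis, fell by 2.01 on the log2 scale, from 577 ± 50.3 to 143 ± 11.1 CPM (SE 0.0508, adjusted p = 1.46e-22). Hmox1, the gene of heme oxygenase 1 (ENSMUSG00000005413, chromosome 8, 75093621 to 75100589), fell by 1.04 (SE 0.0358, adjusted p = 1.06e-19). Alb rose from 34.2 ± 3.50 to 306 ± 13.7 CPM, a log2 change of 3.16.

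In edgeR, 7656 of 13169 genes changed in Hepa1 (58.1%), 3865 up and 3791 down. Without scaling beyond total counts the split was 4515 up and 3169 down, so the balance of directions depends on the scaling. Most changes were small, with a median absolute log2 change of 0.34. At a log2 change of at least 1, 592 genes rose and 273 fell.

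Among the protein-coding genes with the largest rises were Cxcl15, a chemokine gene (4.27), Krt4, a keratin gene (4.17), Fgf1, a fibroblast growth factor gene (3.89), Greb1 (3.85), Scml4 (3.61), Amy1, an amylase gene (3.55), Ceacam2 (3.35) and Iigp1, an interferon-inducible GTPase gene (3.24). Adgre1, the gene of the macrophage antigen F4/80, had 2 reads in control and 118 in ferroptotic medium, a ratio of 59.4 with a 95% counting interval of 16.1 to 496. Col1a2 also passed the rule at 3.37, but without Hepa1 ferroptotic replicate 3 its log2 change was 0.72 with adjusted p = 0.0639. Among the largest falls were those of Sprr2h (-4.11), Crct1 (-3.78), the chemokine gene Cxcl10 (-3.57), the collagenase gene Mmp13 (-3.23), Pglyrp3 (-3.20), Ankrd1 (-3.01), Gm19410 (-3.00), Ccn1 (-2.92) and Cd68 (-2.83). Without Hepa1 ferroptotic replicate 3 the log2 change of Gm19410 was -3.68. Multi-mapped reads were not counted, so the values of Amy1, Sprr2h, Ceacam2 and Iigp1, which have near-identical relatives, are uncertain.

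Proliferation genes rose as a group in Hepa1. All 30 measured G2 and M phase genes rose, with a median log2 change of 2.38 (camera adjusted p = 3.08e-29; adjusted p = 0.183 with an estimated correlation). Kif11 (2.72), Ube2c (2.63), Tpx2 (2.13) and Top2a (2.05) had the smallest adjusted p. Of 30 S phase genes, 24 rose and 1 fell, with a median of 0.68 (adjusted p = 1.02e-08; adjusted p = 0.0746 with an estimated correlation), among them Mcm5 (1.64) and Rrm2 (1.33).

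Genes of the NF-kB, TGF-beta and FGF responses and senescence-linked secretory factors fell in Hepa1. Of 20 NF-kB response genes, 19 fell and 1 rose, with a median of -0.92 (adjusted p = 1.01e-09; adjusted p = 0.0692 with an estimated correlation). Ccl2, a monocyte-attracting chemokine gene, fell by 2.82, Tnfaip3 by 2.00 and Csf1 by 1.24 on the log2 scale. Of 10 genes of the TGF-beta response, 8 fell and 1 rose (median -0.76, adjusted p = 2.29e-06; adjusted p = 0.0692 with an estimated correlation), including Smad7 (-0.94) and Ccn2 (-0.83). Of 27 secretory factors linked to senescence, 18 fell and 5 rose (median -0.52, adjusted p = 0.00046; adjusted p = 0.0746 with an estimated correlation). This list shares members with the NF-kB list, and without shared members its adjusted p was 0.216. Igfbp4, one of its members, rose by a log2 of 1.53. Of 22 genes of the FGF and ERK response, 12 fell and 4 rose (median -0.49, adjusted p = 0.000605; adjusted p = 0.221 with an estimated correlation). Ier3 (-2.05), Junb (-1.51) and Dusp4 (-1.29) fell while Ccnd1, the gene of cyclin D1, rose by a log2 of 1.24.

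Interferon-induced genes moved the other way. Of 29, 25 rose and 3 fell, with a median of 0.91 (adjusted p = 6.70e-06; adjusted p = 0.353 with an estimated correlation). Cmpk2 (2.33) and Oas2 (2.16) rose, whereas Rsad2 fell by 1.99 on the log2 scale.

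Targets of the activator NRF2 and the repressor BACH1 fell in Hepa1. Of 25, 18 fell and 5 rose, with a median of -0.36 (adjusted p = 1.25e-05; adjusted p = 0.346 with an estimated correlation). Besides Slc7a11 and Hmox1, Esd (-1.49) and Taldo1 (-1.36) fell. Tfrc, the transferrin receptor gene, fell by 1.21 on the log2 scale. Fth1, a ferritin gene, rose by a log2 of 0.09 (adjusted p = 0.0134), a call lost without Hepa1 ferroptotic replicate 2 (adjusted p = 0.102).

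Oxidative phosphorylation genes were split by genome. Of 30 nuclear genes of oxidative phosphorylation, 27 rose and 0 fell (median 0.29, adjusted p = 5.96e-09; adjusted p = 0.0692 with an estimated correlation), among them Atp5c1 (0.58) and Ndufb8 (0.60). All 7 measured mitochondrially encoded mRNAs fell (median -0.68, adjusted p = 4.30e-08; adjusted p = 0.0746 with an estimated correlation), with mt-Nd1 at -0.99. Reads on mitochondrial genes made up 0.672% of the counts in control and 0.418% in ferroptotic medium. Of 13 listed mitochondrial mRNAs only 7 were measured, and multi-mapped reads were not counted, so these shares are uncertain. Of 27 PPARA targets and fatty acid oxidation genes, 17 rose and 2 fell (median 0.20, adjusted p = 0.00242; adjusted p = 0.183 with an estimated correlation). Hadh (0.66) rose, and Plin2, a lipid droplet gene, fell by 0.73 on the log2 scale. Of 26 glycolysis and hypoxia genes, 14 fell and 4 rose (median -0.21, adjusted p = 0.0134; adjusted p = 0.346 with an estimated correlation), including Ndrg1 (-1.97) and Hk2 (-1.12).

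Another 8 Hepa1 lists passed the test. Autophagy and lysosome genes fell in 18 and rose in 6 of 31 cases (adjusted p = 0.00181; adjusted p = 0.346 with an estimated correlation), with Sqstm1 at -0.81. Cytosolic ribosomal protein genes fell in 18 and rose in 3 of 39 cases (adjusted p = 0.0123; adjusted p = 0.492 with an estimated correlation). Cholesterol synthesis genes rose in 11 and fell in 1 of 22 cases (adjusted p = 0.0382; adjusted p = 0.221 with an estimated correlation). The heat shock chaperones fell in 7 and rose in 1 of 15 cases (adjusted p = 0.0467; adjusted p = 0.255 with an estimated correlation), a call lost without Hepa1 ferroptotic replicate 2 (adjusted p = 0.0563), with a CPM filter (adjusted p = 0.0601) and with a replicate block (adjusted p = 0.0558). Of 32 hepatocyte markers listed only 7 were measured, and of these 5 rose and 1 fell (adjusted p = 0.0203, and 0.346 with an estimated correlation). Trf, the transferrin gene, was among them at 1.71. Without genes that other lists hold, the hepatocyte markers lost their call (adjusted p = 0.152), as did the heat shock chaperones (adjusted p = 0.0565). Epithelial markers fell in 4 and rose in 1 of 5 cases (adjusted p = 0.0228; adjusted p = 0.351 with an estimated correlation).

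Fibroblast and matrix genes in Hepa1 have to be read beside 1 library. Of 8 fibroblast markers 6 rose (adjusted p = 0.0400; adjusted p = 0.346 with an estimated correlation), and of 21 extracellular matrix genes 14 rose and 3 fell (adjusted p = 0.0400; adjusted p = 0.519 with an estimated correlation). For 36 genes with at least 500 CPM in MEFs and under 0.2 CPM in Hepa1 in control medium, Hepa1 ferroptotic replicate 3 held 0.116% of the MEF level. Ferroptotic replicates 1 and 2, which the choice of genes leaves as free, held 0.00915 and 0.0153%. Without that library the fibroblast list kept its call (adjusted p = 0.0368) and the matrix list lost it (adjusted p = 0.0522). Without genes that other lists hold, the extracellular matrix list lost its call as well (adjusted p = 0.179). The matrix list also lost its call without Hepa1 control replicate 2 (adjusted p = 0.0539) or 3 (adjusted p = 0.0639), and the fibroblast list without Hepa1 control replicate 3 (adjusted p = 0.0639). Col1a1 (0.57) and Sparc (1.16), which Hepa1 cells expressed in control medium at 1515 and 342 CPM, rose.

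Of the genes fixed in advance, Cdkn1a, which encodes the cell cycle inhibitor p21, rose by a log2 of 0.20 in Hepa1 (adjusted p = 3.83e-06). Gdf15, a stress-induced secreted factor gene, had a log2 change of 0.06 and missed the threshold (adjusted p = 0.225). It passed without scaling beyond totals (adjusted p = 0.0293) and without Hepa1 control replicate 3 (adjusted p = 0.0333). Gpx4, the glutathione peroxidase gene that guards against ferroptosis, had a log2 change of -0.02 (adjusted p = 0.768). Fgf21 had 1 and 3 reads in Hepa1 in control and ferroptotic medium, its co-receptor gene Klb 1 and 2, Fgfr1 1 and 12, and Cdkn2a 1 and 2. Of the 12 Fgfr1 reads, 10 came from replicate 3.

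The remaining Hepa1 lists missed the threshold, among them p53 targets (13 of 26 up, 7 down, adjusted p = 0.0646), senescence regulators (8 of 15 up, 3 down, adjusted p = 0.165) and iron handling (9 of 18 up, 6 down, adjusted p = 0.579). Median, mean and test differed in sign for the glutathione, ATF4, unfolded protein response and macrophage lists, none of them called. The FGF21 receptor list had too few measured members to be tested. In camera 20 of 32 lists passed. With an estimated correlation 0 passed, although 21 lists had an unadjusted p under 0.05 with the preset correlation and fry called 29. The TGF-beta list, whose estimated correlation of -0.00693 was below the preset 0.01, lost its call as well. A correlation above the preset therefore does not account for every loss, and the fewer degrees of freedom of that setting also raise p. Adjusted over the list alone, 7 lists gave another count of changed genes, each by 1 gene. The rises and falls became 25 and 1 for S phase, 6 and 18 for NRF2 and BACH1 targets, 25 and 4 for interferon, and 5 and 19 for secretory factors. They became 4 and 13 for FGF and ERK, 7 and 18 for autophagy, and 4 and 15 for glycolysis.

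**Figure D2:**
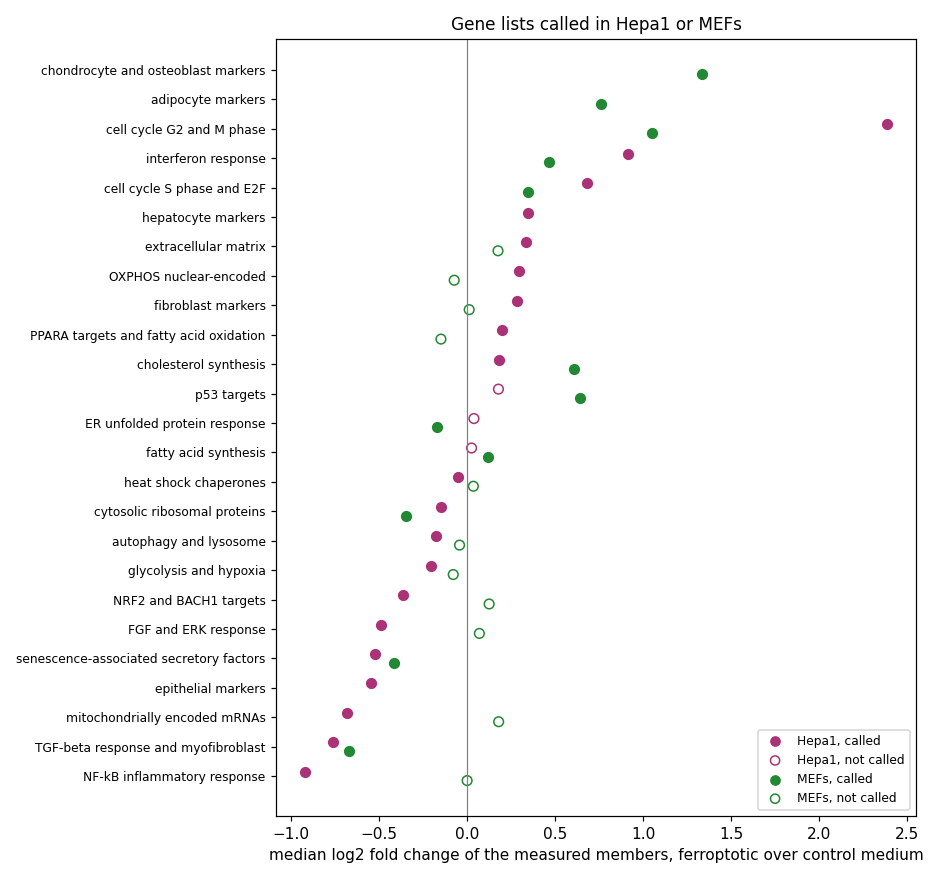
Median log2 fold change of the measured members, ferroptotic over control medium (x axis), for each gene list called in Hepa1 or in MEFs (y axis); filled points passed camera at the preset correlation and open points did not. G2 and M phase genes lie at 2.38 in Hepa1 and 1.05 in MEFs, and TGF-beta response genes at -0.76 and -0.67.

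In MEFs, p53 targets, cholesterol synthesis genes and G2 and M phase genes were higher in the ferroptotic medium, and TGF-beta response and myofibroblast genes were lower. These list calls were lost with an estimated correlation (adjusted p = 0.0890, 0.307, 0.188 and 0.125). Gdf15 went from 8.13 ± 0.804 to 27.5 ± 2.67 normalised CPM (SD, n = 3), a log2 change of 1.76 (SE 0.0780, adjusted p = 5.22e-26). Cdkn1a rose from 198 ± 1.98 to 386 ± 7.65 CPM, a log2 change of 0.96 (SE 0.0285, adjusted p = 1.38e-33). Hmox1 rose from 1911 ± 44.3 to 3262 ± 63.8 CPM, a log2 change of 0.77. Itga11, a collagen-binding integrin gene, fell by 2.05 on the log2 scale, from 2245 ± 33.3 to 543 ± 9.43 CPM.

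In edgeR, 7943 of 14441 genes changed in MEFs (55.0%), 4009 up and 3934 down, with a median absolute log2 change of 0.34. Without scaling beyond total counts the split was 5211 up and 2957 down, so the balance of directions depends on the scaling. At a log2 change of at least 1, 632 genes rose and 344 fell.

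The largest rises in MEFs were those of Scg2, a secretory granule protein gene (6.02), Phex, a bone mineral regulator gene (4.32), Crispld1 (4.15), the prolactin receptor gene Prlr (4.13), Lrrtm1 (4.09), Chrdl1, a BMP antagonist gene (4.05), the cartilage collagen gene Col9a3 (3.94), Wdr72 (3.66), Ano5 (3.62) and Fras1 (3.58). The falls were led by Mcpt8, with 231 reads in control and 2 in ferroptotic medium, a ratio of 119 with a 95% counting interval of 32.6 to 989. They went on with the granzyme gene Gzme (-5.98), Angptl7 (-5.03), Alkal1 (-4.74), Kcnj15 (-4.45), Lgr6 (-4.19), Dio2, the gene of a thyroid hormone deiodinase (-4.06), Ramp3 (-3.80), Nfe2l3 (-3.71) and Prss35 (-3.62). Some of these folds are imprecise. In ferroptotic medium, replicate 3 and the other 2 replicates together held 3 and 4 reads of Gzme, 3 and 2 of Angptl7, and 4 and 4 of Lgr6. Without MEF ferroptotic replicate 3 the log2 change was -5.38 for Dio2 and -5.66 for Angptl7. Mcpt8 and Gzme have close relatives, so their counts are uncertain.

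TGF-beta response and myofibroblast genes fell together in MEFs. Of 24, 23 fell and 1 rose, with a median of -0.67 (adjusted p = 2.39e-17; adjusted p = 0.125 with an estimated correlation). Ccn2 (-1.25) fell with Itga11, and Postn, the periostin gene, was the member that rose (1.58). Of 21 genes of the unfolded protein response in the endoplasmic reticulum, 15 fell and 0 rose (median -0.17, adjusted p = 4.74e-05; adjusted p = 0.125 with an estimated correlation), including Calr (-0.38) and Dnajb9 (-0.50). Cytosolic ribosomal protein genes fell in 31 and rose in 1 of 40 cases (median -0.34, adjusted p = 8.71e-10; adjusted p = 0.350 with an estimated correlation), with Rps20 at -0.71. Ribosomal proteins have many pseudogenes that share reads with them.

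Targets of p53 and cell cycle genes both rose in MEFs. Of 26 p53 targets, 22 rose and 1 fell, with a median of 0.64 (adjusted p = 1.72e-14; adjusted p = 0.0890 with an estimated correlation), among them Trp53inp1 (1.39) and Ccng1 (0.75). Of 30 G2 and M phase genes, 29 rose and 1 fell, with a median of 1.05 (adjusted p = 7.89e-09; adjusted p = 0.188 with an estimated correlation). Mki67 (2.06) and Cenpf (1.93) rose, and Cdk1, the mitotic kinase gene, was the member that fell (-0.24). S phase genes rose in 18 and fell in 2 of 30 cases (median 0.35, adjusted p = 0.00286; adjusted p = 0.221 with an estimated correlation). A replicate block ended this call of the list cell cycle S phase and E2F (adjusted p = 0.0642).

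Genes of cholesterol and fatty acid synthesis and markers of adipocytes, chondrocytes and osteoblasts rose in MEFs. Of 25 cholesterol synthesis genes, 22 rose and 1 fell, with a median of 0.61 (adjusted p = 7.54e-09; adjusted p = 0.307 with an estimated correlation), including Hmgcs1 (1.17). Fatty acid synthesis genes rose in 12 and fell in 5 of 21 cases (adjusted p = 0.0116; adjusted p = 0.383 with an estimated correlation), with Elovl6 at 1.35. Of 8 adipocyte markers 5 rose and 1 fell (median 0.76, adjusted p = 0.00129; adjusted p = 0.135 with an estimated correlation), including Lpl (2.31), Plin4 (2.12) and Pparg (1.23). Of 11 chondrocyte and osteoblast markers 9 rose and 1 fell (median 1.34, adjusted p = 3.36e-05; adjusted p = 0.125 with an estimated correlation), with Cnmd (1.83) and Comp (1.81) up and Spp1, the osteopontin gene, down (-1.51). PPARA targets and fatty acid oxidation genes missed the threshold, with 16 of 30 lower and 6 higher (median -0.15, adjusted p = 0.0851).

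Interferon-induced genes rose in 20 and fell in 0 of 23 cases in MEFs (median 0.47, adjusted p = 0.000428; adjusted p = 0.355 with an estimated correlation). Of 35 secretory factors linked to senescence, 22 fell and 11 rose (median -0.41, adjusted p = 0.00984; adjusted p = 0.383 with an estimated correlation). Timp1 (-1.37) fell, while Igfbp5, an IGF-binding protein gene, rose from 86.0 ± 7.54 to 813 ± 41.8 CPM.

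Lists of redox defence and iron genes were not called by camera in MEFs. Of 27 targets of NRF2 and BACH1, 15 rose and 8 fell and the list missed the threshold (median 0.13, adjusted p = 0.0652). So did glutathione and selenoprotein genes (6 of 22 up, 10 down, adjusted p = 0.353) and iron handling (8 of 18 up, 6 down, adjusted p = 0.683). In fry, NRF2 and BACH1 targets (adjusted p = 0.00145) and iron handling (adjusted p = 0.00739) passed as up. Glutathione and selenoprotein genes passed fry as down (adjusted p = 0.000967). Slc40a1, the iron exporter gene, rose by a log2 of 1.53, Slc7a11 by 0.78, Fth1 by 0.45 and Tfrc by 0.20. Gpx4 had a log2 change of -0.10 (adjusted p = 0.155). Cdkn2a, the gene of p16 and p19ARF, rose by 0.36. Bach1 fell by 0.11 (adjusted p = 0.0126), a call lost without MEF control replicate 1 (adjusted p = 0.121) and without MEF ferroptotic replicate 3 (adjusted p = 0.121). It was also lost without scaling beyond totals (adjusted p = 0.356) and in DESeq2 (adjusted p = 0.0627). Fgf21 had 53 and 51 reads in the control and ferroptotic MEFs and Klb 0 in both. Fgfr1 stood at 431 and 447 CPM (log2 0.05, adjusted p = 0.100), and it passed without scaling beyond totals (adjusted p = 0.000128). Other receptor genes were looked at after their values were seen. Fgfr2 went from 200 ± 4.20 to 285 ± 3.38 plain CPM and Fgfr3 from 3.46 ± 0.491 to 6.62 ± 0.556 (SD, n = 3). Fgfr4 had 20 and 16 reads and Kl 2 and 1.

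Other MEF lists also missed the threshold, such as senescence regulators (6 of 18 up, 5 down, adjusted p = 0.480) and mitochondrially encoded mRNAs (4 of 7 up, 1 down, adjusted p = 0.0564). Median, mean and test differed in sign for the ATF4, NF-kB, gluconeogenesis, fibroblast and neural lists, none of them called. In camera 12 of 32 lists passed. With an estimated correlation 0 passed, although 18 had an unadjusted p under 0.05 with the preset correlation and fry called 29. Adjusted over the list alone, 6 lists gave another count of changed genes, each by 1 gene. The rises and falls became 23 and 1 for p53 targets, 10 and 1 for chondrocyte and osteoblast markers, and 20 and 1 for interferon. They became 19 and 2 for S phase, 15 and 9 for NRF2 and BACH1 targets, and 7 and 5 for senescence regulators.

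The next question was which genes responded differently in the 2 cell types, tested as the MEF response minus the Hepa1 response. Cell type and Bach1 genotype change together in this design, so a difference can come from either. Hmox1 and Slc7a11 fell in Hepa1 and rose in MEFs, with interaction log2 values of 1.81 (SE 0.0548, adjusted p = 4.09e-29) and 2.79 (SE 0.172, adjusted p = 3.88e-18). Gdf15 (1.69), Tfrc (1.41), Cdkn1a (0.76) and Fth1 (0.36) were also higher in the MEF response. In edgeR, 6911 of 15627 genes differed (44.2%), 3267 with the higher and 3644 with the lower response in MEFs. This balance turned over without scaling beyond total counts (3503 and 3420) and among genes tested in both cell types (3413 and 3315).

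The list of NRF2 and BACH1 targets was higher in the MEF response for 19 of 27 genes and lower for 4 (median 0.52, adjusted p = 1.33e-07; adjusted p = 0.160 with an estimated correlation), with Nqo1 at 1.99 and Abcc4 at 1.35. All 7 measured mitochondrially encoded mRNAs, of 13 listed, were higher (median 0.96, adjusted p = 1.96e-10, and 0.0920 with an estimated correlation). Of 30 nuclear genes of oxidative phosphorylation, 26 were lower (median -0.38, adjusted p = 1.96e-10; adjusted p = 0.0920 with an estimated correlation). Of 30 G2 and M phase genes, 27 were lower in the MEF response (median -1.11, adjusted p = 5.05e-09; adjusted p = 0.318 with an estimated correlation). Of 26 p53 targets, 19 were higher and 2 lower (adjusted p = 1.38e-08; adjusted p = 0.0920 with an estimated correlation), with Plk2 at 1.72. Of 22 NF-kB response genes, 13 were higher and 1 lower (adjusted p = 0.000127; adjusted p = 0.0920 with an estimated correlation), with Relb at 1.38.

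In all, 17 of 37 lists differed, 10 higher and 7 lower in the MEF response. With an estimated correlation 0 passed, although 19 had an unadjusted p under 0.05 with the preset correlation and fry called 24. Adjusted over the list alone, 6 lists gave another count, by at most 2 genes. The higher and lower counts became 0 and 29 for G2 and M phase, 4 and 14 for the unfolded protein response, and 4 and 20 for PPARA targets. They became 10 and 13 for secretory factors, 5 and 13 for interferon, and 8 and 18 for extracellular matrix.

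Among the genes with the largest interaction several had hardly any reads in 1 cell type, so reads are given in place of folds. In MEFs, reads in control and ferroptotic medium were 0 and 17 for Ppef1, 2 and 12 for Crct1, 2 and 19 for Zan, 0 and 8 for Cxcl10 and 0 and 10 for Cldn3. For 19 genes with at least 100 CPM in Hepa1 and under 0.2 CPM in MEFs in control medium, MEF ferroptotic replicate 3 held 0.120% of the Hepa1 level, against 0.0253 and 0.0170% in replicates 1 and 2. Without it, Cxcl10 (adjusted p = 0.0806) and Cldn3 (adjusted p = 0.276) lost their calls. In Hepa1, reads were 0 and 12 for Sfrp1, 2 and 62 for Fbln2, 0 and 18 for Thy1, 0 and 9 for Nox4 and 0 and 1 for Alkal1. Without Hepa1 ferroptotic replicate 3, Sfrp1 (adjusted p = 0.163), Thy1 (adjusted p = 0.205), Alkal1 (adjusted p = 1.00) and Fgfr1 (adjusted p = 0.526) lost their calls. Fbln2 (adjusted p = 0.00227) and Nox4 (adjusted p = 0.00578) kept theirs on 7 and 3 reads in the other Hepa1 ferroptotic libraries. The interaction log2 of Fbln2 went from -6.28 to -3.78, and that of Nox4 from -5.93 to -5.00. Those libraries also held MEF genes at 0.00915 and 0.0153% of the MEF level, so the calls do not show a response of Hepa1 cells.

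**Figure D3:**
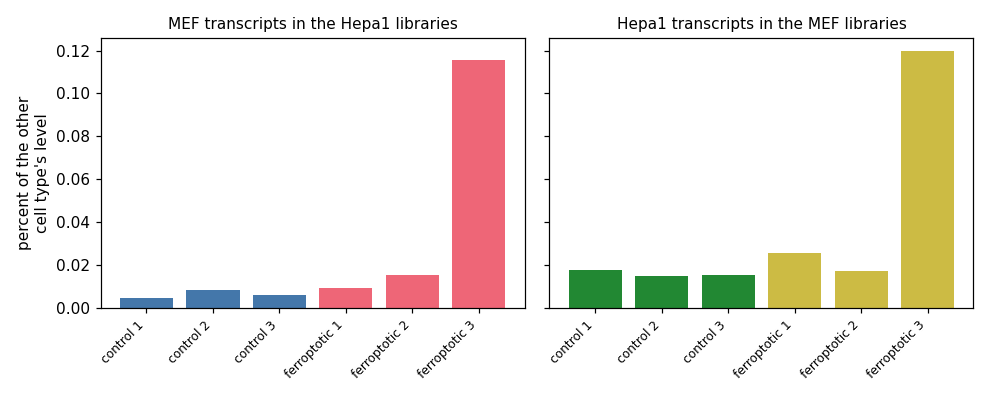
Summed level of genes abundant in the other cell type as a percentage of their level there (y axis, 1 bar per library), for MEF genes in the 6 Hepa1 libraries (left) and Hepa1 genes in the 6 MEF libraries (right), chosen to be under 0.2 CPM in the control libraries shown, whose bars are low by that choice. The ferroptotic replicate 3 of each cell type stands apart, at 0.116% in Hepa1 and 0.120% in MEFs.

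Many genes changed in both cell types. Steap4, a metalloreductase gene, rose by a log2 of 2.57 in Hepa1 and 3.07 in MEFs. Enpp2, the autotaxin gene (2.73 and 2.49), Abca8a (2.72 and 2.35), Fgf1 (3.89 and 2.20) and Plekhg4 (3.11 and 2.06) rose in both. Mmp13 (-3.23 and -3.78), Ankrd1 (-3.01 and -2.08), Tcim (-1.90 and -1.82), Klra4 (-1.58 and -2.88) and Lcn2, the lipocalin 2 gene (-1.66 and -1.58), fell in both. The MEF folds of Mmp13 and Klra4 are imprecise. MEF ferroptotic replicate 3 and the other 2 together held 3 and 3 reads of Mmp13 and 1 and 5 of Klra4.

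Of 12042 genes tested in both cell types, 4275 were called in both, 2436 in the same direction (57.0%) and 1839 in opposite directions. Rises were shared by 1187 genes where independence gives 926 (odds ratio 1.68, 95% interval 1.54 to 1.83, Fisher's exact test, 2-sided, p = 1.56e-31), and falls by 1249 where it gives 987 (odds ratio 1.65, 95% interval 1.52 to 1.80, Fisher's exact test, p = 1.07e-30). Genes up in Hepa1 and down in MEFs numbered 917 against 978 (odds ratio 0.884, Fisher's exact test, p = 0.00679). Those down in Hepa1 and up in MEFs numbered 922 against 935 (odds ratio 0.973, Fisher's exact test, p = 0.555). Genes are not independent replicates, so these p-values describe overlap across genes. Of 141 genes with a log2 change of at least 1 in both, 126 moved the same way.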

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

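The tests of RNA carried between cell types, of induction, of the source of the Bach1 reads, of Bach1 genotype, of the scaling of the libraries, of the NRF2 and BACH1 list without Hepa1 ferroptotic replicate 3, and of other splits of the samples were chosen after the results were seen. The comparison with other fibroblasts and the correction for GC content and length on the list of NRF2 and BACH1 targets were planned before their values were seen.

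The response to the ferroptotic medium differed between Hepa1 and MEFs for 6911 genes. Of 200 possible splits of the samples 100 were run. Among these 1 gave as many genes, the real one, and the highest of the others run gave 2732. The other splits mix media within a cell type, which puts the response to the medium into the spread and lowers their counts, so they do not exclude chance. For the counts within a cell type the 10 possible splits are too few for a share under 0.05: 1 of 10 gave as many in Hepa1 (7656, highest other 0) and 1 of 10 in MEFs (7943, highest other 0).

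Targets of NRF2 and BACH1 moved apart in the cell types (adjusted p = 1.33e-07), with a median interaction log2 of 0.52, a call lost with an estimated correlation (adjusted p = 0.160). With trends of GC content and transcript length removed the median was 0.53, which argues against these trends as the whole cause. The lowest median under the other scalings was 0.53, and without Hepa1 ferroptotic replicate 3 it was 0.59. These values decide little. TMM factors within the cell types ran only from 0.970 to 1.03, and that library held 0.116% of the MEF level, so neither change could move the median far. Bach1 genotype may account for the difference, because BACH1 represses these genes, and it stays open: 0 groups hold the other Bach1 genotype of the same cell type, so genotype and cell type cannot be told apart. In Hepa1, Bach1 RNA went from 142 to 121 plain CPM while these targets fell, so the RNA level of the repressor does not explain their fall. Among these genes and the other fixed genes the interaction log2 was 1.81 for Hmox1, 2.79 for Slc7a11, 1.41 for Tfrc and 0.36 for Fth1.

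Fibroblast transcripts stood higher in Hepa1 ferroptotic replicate 3 than in the other Hepa1 libraries. RNA or reads from the MEF samples could account for them and stay open: the upper quartile of the ratio to the MEF level was 1.90 times the lower. That level was the mean over both media, whose profiles differ, which can itself widen the quartiles, so this ratio cannot decide. Other fibroblasts, such as cells carried over with the medium, stay open too, since the chi-square per degree of freedom was 1.68 against MEFs in control medium, between the bounds written for and against them, and 16.6 against MEFs in ferroptotic medium. Induction in Hepa1 cells by the medium is argued against by the share in the other ferroptotic libraries, which was 0.106 of that in replicate 3 (95% interval 0.0892 to 0.123). The bound first written, under 0.1, was narrowly missed, and both the gene set and the decision rule of this test were set after a value had been seen.

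Bach1 was read in the MEFs labelled knockout, and its interaction log2 was 0.16. Reads from Hepa1 cells are argued against by Alb, which had 0 reads in the MEF libraries, whereas the share of Hepa1 RNA needed for the Bach1 level would have brought Alb to 18.1 CPM. Bach1 RNA from the re-expressing cells that conditioned the medium is argued against by a ratio of ferroptotic to control medium of 0.969. Transcription of the exons that the knockout allele keeps may account for the reads, and it stays open because the gene counts hold 0 exon-level values. The Bach1 interaction call was lost without Hepa1 control replicate 2 (adjusted p = 0.0526), Hepa1 ferroptotic replicate 2 (adjusted p = 0.103), MEF control replicate 3 (adjusted p = 0.106) or MEF ferroptotic replicate 2 (adjusted p = 0.0646).

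Other genes fixed in advance also responded differently, with interaction log2 values of 0.76 for Cdkn1a and 1.69 for Gdf15. Fgfr1 had a fitted value of -3.04, which rests on 1 and 12 reads in Hepa1, a ratio of 12.1 with a 95% counting interval of 1.79 to 516. The Fgfr1 call was lost without Hepa1 control replicate 1 (adjusted p = 0.0606) or 3 (adjusted p = 0.0562) or Hepa1 ferroptotic replicate 3 (adjusted p = 0.526). The fitted value of Fgfr1 was -4.79 without Hepa1 control replicate 2 and -1.20 without Hepa1 ferroptotic replicate 3.

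Energy, growth and stress lists differed between the cell types as well. The adjusted p was 1.96e-10 for nuclear genes of oxidative phosphorylation and 1.96e-10 for mitochondrially encoded mRNAs. It was 5.05e-09 for G2 and M phase genes, 1.38e-08 for p53 targets and 0.000127 for NF-kB response genes. With an estimated correlation these became 0.0920, 0.0920, 0.318, 0.0920 and 0.0920. Cytosolic ribosomal protein genes were lower in the MEF response for 23 of 40 and higher for 1 (adjusted p = 0.000244; adjusted p = 0.349 with an estimated correlation). PPARA targets were lower for 19 of 30 and higher for 4 (adjusted p = 0.00145; adjusted p = 0.277 with an estimated correlation). Cholesterol synthesis genes were higher for 12 of 25 and lower for 2 (adjusted p = 0.00462), and fatty acid synthesis genes higher for 12 of 21 and lower for 3 (adjusted p = 0.0216). With an estimated correlation both calls were lost (adjusted p = 0.349 and 0.175). Unfolded protein response genes were lower for 12 of 21 and higher for 4 (adjusted p = 0.0181), a call lost without Hepa1 control replicate 1 (ER unfolded protein response, adjusted p = 0.0522) and with an estimated correlation (adjusted p = 0.599). FGF and ERK response genes were higher for 12 of 26 and lower for 2 (adjusted p = 0.0181, and 0.349 with an estimated correlation).

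Another 5 lists, each with at least 1 member unread in a whole group, also passed. Acute-phase and complement genes were lower in the MEF response for 7 of 13 (adjusted p = 0.00688), hepatocyte markers for 4 of 8 (adjusted p = 0.0134), and adipocyte markers were higher for 5 of 9 (adjusted p = 0.0385; adjusted p = 0.0618 for adipocyte markers with a CPM filter). With an estimated correlation these calls were lost (adjusted p = 0.175, 0.130 and 0.175). Heat shock chaperones were higher for 7 of 18 and lower for 1 (adjusted p = 0.0409, and 0.349 with an estimated correlation). Genes of autophagy and lysosome were higher for 16 of 32 and lower for 7 (adjusted p = 0.0360), a call lost for autophagy and lysosome without MEF ferroptotic replicate 3 (adjusted p = 0.0553) and with an estimated correlation (adjusted p = 0.693).

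Genes read almost in 1 cell type alone had the largest interaction values. The adjusted p was 0.000634 for Cxcl10, 9.00e-07 for Crct1, 5.33e-05 for Ppef1, 0.00255 for Cldn3 and 8.35e-07 for Zan, which were higher in the MEF response. It was 0.0443 for Alkal1, 0.00018 for Sfrp1, 1.25e-07 for Fbln2, 0.000116 for Thy1 and 4.03e-05 for Nox4, which were lower. Without MEF ferroptotic replicate 3 it was 0.0806 for Cxcl10 and 0.276 for Cldn3, and without Hepa1 ferroptotic replicate 3 it was 0.163 for Sfrp1, 0.205 for Thy1, 1.00 for Alkal1, 0.00227 for Fbln2 and 0.00578 for Nox4. For Fbln2 and Nox4 only 7 and 3 reads then remained in Hepa1 in ferroptotic medium. Alkal1 also lost its call without MEF control replicate 2 (adjusted p = 0.0543), without MEF ferroptotic replicate 2 (adjusted p = 0.0519) and without any 1 of the Hepa1 controls (adjusted p = 0.0607 to 0.0631).

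Reads on no annotated gene, which the comparisons do not use, made up 2.51% of the counts of MEFs in ferroptotic medium against 2.06% in control medium.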

How the results depend on the processing

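The minimum fold of 1.2, the GC and length offsets, the genes tested in both cell types and the lists without shared members were added after seeing the data. Counts of changed genes kept within 1.5 times under the other scalings, filters and tests run. At a log2 change of at least 1, 865 genes changed in Hepa1 and 976 in MEFs, and against a minimum fold of 1.2 there were 3272 and 3267, because these settings ask for a larger effect. In camera with an estimated correlation 0 lists were called in Hepa1, 0 in MEFs and 0 for the interaction, while fry called 29, 29 and 24 of them. Some lists lost their calls although their estimated correlation was below the preset 0.01. Examples are the TGF-beta list in Hepa1 (-0.00693) and the adipocyte markers in MEFs (-0.0694). A correlation above the preset therefore does not account for every loss, and the fewer degrees of freedom of that setting also raise p. Without scaling beyond total counts the split was 4515 up and 3169 down in Hepa1 and 5211 up and 2957 down in MEFs. Leaving out 1 library gave 6980 to 7634 changed genes in Hepa1, 7369 to 7629 in MEFs and 6479 to 6748 for the interaction.

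The replicate numbers were not treated as pairs in the main tests. With a replicate block 7437 genes changed in Hepa1, 8073 in MEFs and 6867 for the interaction, 4254 were called in both, and the list counts were 19, 12 and 17. With the block the S phase list in MEFs (cell cycle S phase and E2F, adjusted p = 0.0642) and the heat shock chaperones in Hepa1 (adjusted p = 0.0558) lost their calls.

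Krt18, a keratin gene, was the named gene with a call whose direction reversed. Its interaction log2 was 2.12 (adjusted p = 0.00753) and -0.85 without MEF ferroptotic replicate 3 (adjusted p = 0.400). Leaving out other MEF libraries gave up to 2.64. MEF ferroptotic replicate 3 held 47 of the MEF reads of Krt18 in ferroptotic medium, where the others held 2 and 2. The Krt18 call was also lost in the DESeq2 Wald test (2.10, adjusted p = 0.201). Cdkn2a, which was not called, also changed sign, from an interaction log2 of -0.38 to 2.10 without Hepa1 ferroptotic replicate 3. That library held the 2 Cdkn2a reads of Hepa1 in ferroptotic medium. Under at least 1 setting, calls changed among others for Gdf15, Fth1 and Col1a2 in Hepa1 and for Bach1 and Fgfr1 in MEFs. For the interaction they changed for Alkal1, Bach1, Cldn3, Cxcl10, Fgfr1, Foxa1, Krt18, Nes, Sfrp1 and Thy1.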

Other observations

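The test of the MEF ferroptotic library for Hepa1 transcripts was chosen after the results were seen, and both tests of YAP and TEAD targets were planned before their values were seen.

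Genes that the coactivator YAP and its partner TEAD drive were tested as a list in both cell types. Ccn1, Ccn2 and Ankrd1, which are such targets, had fallen in both, and these were left out of the test along with the other members already seen. Lower YAP and TEAD activity may be shared by the cell types, but the list calls below were lost with an estimated correlation (adjusted p = 0.105 in Hepa1 and 0.122 in MEFs). The median log2 change of the remaining targets was -0.28 in Hepa1 and -0.31 in MEFs. Of 14 remaining targets in Hepa1, 12 fell and 2 rose (camera adjusted p = 0.000933). Of 16 in MEFs, 10 fell and 4 rose (adjusted p = 0.001). This is a hypothesis found and tested on the same samples.

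Hepa1 transcripts stood higher in MEF ferroptotic replicate 3 than in the other MEF libraries. It had 159 reads on the 19 Hepa1 genes, which were chosen to be low in MEFs in control medium, where MEF ferroptotic replicates 1 and 2 had 31 and 21. The profile of these reads was set against Hepa1 in control and in ferroptotic medium. Over the same 7 genes the chi-square per degree of freedom was 0.489 and 0.512. These genes had enough expected reads under both profiles, a choice that can leave out genes that differ between them. With each profile's own genes the value was 0.489 over 10 genes for control and 2.24 over 12 genes for ferroptotic medium. Those gene sets differ, so the reads were not assigned to a medium.

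Some genes changed strongly in opposite directions, and these were chosen after their values were seen. Ccl2 fell by 2.82 on the log2 scale in Hepa1 (SE 0.0703) and rose by 2.06 in MEFs (SE 0.374). The MEF value rests on few reads, 28 in ferroptotic replicate 3 and 41 in the other 2 ferroptotic replicates together. Reps2 (-1.27 and 2.20) and Slpi, a protease inhibitor gene (-1.11 and 1.83), also fell in Hepa1 and rose in MEFs. Trf (1.71 and -1.37) and the sulfatase gene Sulf1 (1.61 and -1.73) did the opposite.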
